A study of Mus musculus with 2 samples.

How the data were processed

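RNA abundance was measured in E14 cells, a mouse embryonic stem cell line kept in serum and leukemia inhibitory factor on gelatin without a stated feeder layer. Per the labels, the cells received a lentivirus with a non-targeting shRNA (shCtrl) or with shSin3a-1, an shRNA against Sin3a, and total RNA was taken after selection with puromycin. Each group had 1 array, so neither biological nor technical replicates existed, and both arrays were assigned to their groups by the shRNA named in the labels. Per the labels, the RNA was amplified from the 3' end and labelled with biotin for an Affymetrix 3' expression array, which reported 45101 probe sets, of which 64 were control probe sets.

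The deposited values were intensity signals on a linear scale, which the authors computed with MAS5 in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. The deposited signals ran from 0.247 to 31174 on the shCtrl array and from 0.0502 to 28943 on the shSin3a-1 array, and both had a trimmed mean of 500 after 2% of the values were left off at each end, which is the usual MAS5 scaling. Detection calls were not used here. MAS5 subtracts mismatch signals and so spreads widely near background, which makes ratios of dim probe sets unreliable. The number of arrays limits the precision.

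Gene names came from the platform annotation, in which 34958 probe sets had exactly 1 symbol, 932 had several and 9211 had none; probe sets with several symbols or none were not named. Symbols were updated through the Entrez gene identifier with a RefSeq gene table of assembly GRCm38.p6, in which 34754 of the probe sets with 1 symbol matched. The files name no genome build, so no coordinates are given, and the table's gene lengths served a check of gene span only.

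Signals were taken to log2, and control probe sets were left out of scaling and gene counts. The rule fixed beforehand was to keep the deposited scaling unless the log2 medians of the arrays differed by over 0.1. They were 6.17 and 6.06, a difference of -0.11 (shSin3a-1 minus shCtrl), so each array was centred on its median, which raises every shSin3a-1 difference by that shift. The median lies near background on these arrays: at the 75th percentile the deposited arrays differed by 0.0077. Small differences are therefore read relative to this shift. List medians that turn with the deposited scaling are named, and so are some single genes. A gene was represented by its probe set with the highest mean log2 signal. It was kept if its brighter value reached the 60th percentile of that array, which left 9782 of 18193 genes. Values under the 40th percentile of an array were set to it, and a fold with the dimmer side at this floor is a lower bound ("at least").

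With 1 array per group no p-value, standard error or SD over samples was computed. Genes were counted as higher or lower at a fixed size of 2-fold. For 30 gene lists, the median log2 difference of the kept members was placed as a percentile among 10000 random lists of the same size, drawn from other kept genes and matched on signal decile. This percentile describes these 2 arrays and does not test the condition. A list was said to stand apart below percentile 2.5 or above 97.5, and lists with fewer than 5 kept members received values only. The gene lists, the rules and the alternatives were fixed before the data were examined, except where stated. The lists held 664 entries, 60 of which had no probe set with 1 symbol. The genes named are Sin3a, Lefty1, Tet1, Pou5f1, Nanog and Sox2, whatever their values; the 12 kept genes with the highest and the 12 with the lowest log2 difference; and from each list up to 3 members per direction at 2-fold or more, or else its member with the largest difference. Other named genes were chosen after their values were seen. Signals are quoted as deposited, and folds and log2 differences are those after centring.

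The alternatives were the deposited scaling, scaling on the 75th percentile, quantile and loess scaling, other floors and filters, the mean of all probe sets of a gene, probe sets without a suffix for shared sequence, an offset before log2, other fold thresholds, agreement of all probe sets, unmatched random lists and the mean of a list. A suffix (_a, _s or _x) was taken as a mark of sequence shared between transcripts, of the same gene or of several. Probe sets with it were left out only where the gene had another probe set without it. Genes with suffixed probe sets only, such as Sox17 and Zfp935, kept theirs. Random lists matched on gene span and a filter at the 90th percentile were added after the data were seen. The procedure was tested on a simulated pair of arrays with the spread of the real pair. Of 200 genes changed by 1.5 on the log2 scale, among 9765 tested, 89.0% passed 2-fold in the right direction. Noise alone carried 356 unchanged genes (3.72%) past 2-fold, although the noise was taken from the real pair and so includes any real differences. Of 200 unshifted lists of 15 genes 4.5% fell outside the central 95% of random lists, and 100% of 50 lists shifted by 0.7 lay above it. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.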

Results

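Messenger RNA levels were compared between E14 mouse embryonic stem cells carrying a control shRNA (shCtrl) and cells carrying an shRNA against Sin3a (shSin3a-1), the scaffold of a histone deacetylase complex. The comparison asks which transcripts differ when Sin3a is depleted in pluripotent cells. Each group was 1 array, and a single shRNA was used, so no difference below has a replicate check. The log2 signals of 9782 kept genes correlated across genes with r = 0.967 between the arrays; genes are not independent replicates. The 3' to 5' signal ratio, a measure of RNA integrity, was 0.824 in shCtrl and 0.809 in shSin3a-1 for GAPDH, and 1.46 and 1.33 for beta-actin.

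Sin3a itself was lower in the knockdown. The signal of its brightest probe set was 3072 in shCtrl and 534 in shSin3a-1, a log2 difference of -2.41, or 18.8% of the control level after centring. Its other kept probe sets were also lower, with log2 differences of -2.30 and -1.63. The array labelled shSin3a-1 thus had less Sin3a messenger RNA than the array labelled shCtrl in 3 of 3 probe sets.

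Most kept genes differed little between the arrays: 8124 of 9782 (83.1%) lay within 1.5-fold. At 2-fold or more, 238 genes were higher and 197 were lower in shSin3a-1, so that 54.7% of these genes were higher. The balance of directions depended on the scaling. With the deposited scaling 166 genes were higher and 273 lower (37.8% higher). Scaling on the 75th percentile gave 156 and 282 (35.6%), quantile scaling 169 and 242 (41.1%), and loess scaling 180 and 237 (43.2%). All 4 of these scalings gave more lower than higher genes, against the balance after centring. The 42 spike-in control probe sets had a median log2 difference of -0.0028 as deposited and of 0.11 after centring. The kept genes had a median log2 difference of 0.07 after centring and of -0.03 as deposited. Counts of list members above or below 0 refer to centred values, and members just above 0 turn below it with the deposited scaling. Counts of list members past or within 2-fold refer to each gene's brightest probe set. Other kept probe sets of a gene can pass 2-fold or differ in direction. Most of the differences lay among dim genes: 10.4% of the 2590 genes whose brighter value lay between the 60th and 75th percentile passed 2-fold, against 3.31% of 4015 genes between the 75th and 90th and 1.04% of 3177 genes above. Noise as wide as the spread of these arrays, which includes any real differences, carried 356 unchanged genes past 2-fold in a simulated pair, so many single genes among the 435 have little weight by themselves. Of 116 genes with the brightest probe set at 2-fold or more and a second kept probe set, 103 (88.8%) differed in the same direction in both, and 49 passed 2-fold in both.

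**Figure D1:**
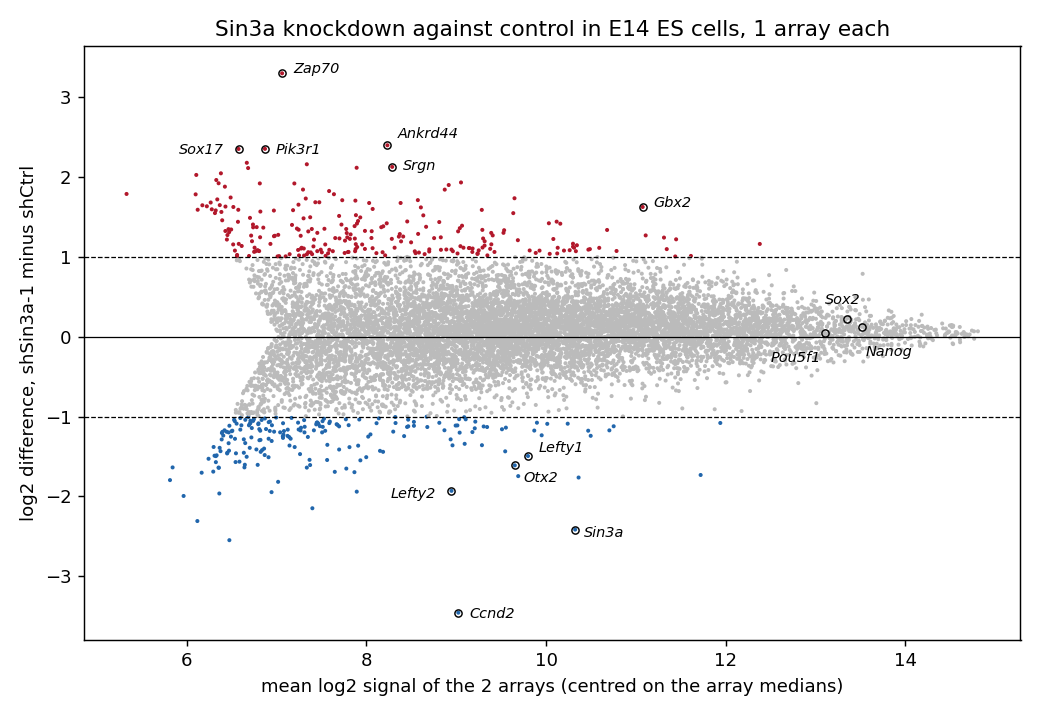
Each point is 1 of the 9782 kept genes, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference, shSin3a-1 minus shCtrl after centring, on the y axis. Dashed lines mark 2-fold, the 238 genes above them are red and the 197 below them blue; with the deposited scaling these numbers are 166 and 273. Ccnd2 (-3.45) and Sin3a (-2.41) lie far below genes of like signal, and Pou5f1, Nanog and Sox2 lie near 0.

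Ccnd2, which encodes the G1 cyclin D2, had the lowest difference of all kept genes. Its signal was 1788 in shCtrl and 151 in shSin3a-1 (11.0-fold lower, log2 difference -3.45), and 6 of 6 kept probe sets were lower, from -3.45 to -2.54. Lefty2, a secreted inhibitor of Nodal, was 3.81-fold lower, with signals of 1000 and 243. Among the other 12 lowest genes, Zfp865 (-2.15), Lrmp (-1.95), Calb2 (-1.94), a calcium-binding protein, and Ltbp3 (-1.82), a binding protein of latent TGF-beta, were measured above the floor on both arrays. Gm9564, Kif26a, Pnmt, Pmel and BC028528 were at the floor in shSin3a-1 and at least 5.85-, 4.95-, 3.98-, 3.90- and 3.47-fold lower. When all probe sets of a gene were averaged, Pnmt and Ltbp3 were under the floor on both arrays and had no measured difference, and Zfp865 was at the floor in shSin3a-1 with a bound of -0.61.

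Among the higher genes, Zap70, a tyrosine kinase of antigen receptor signalling, led with a signal of 41.7 in shCtrl and 427 in shSin3a-1, at least 9.83-fold. This rests on 1 of its 3 probe sets: the others did not reach the filter, and the mean of all 3 gave only a lower bound of 0.23 on the log2 difference, with 1 array at the floor. Ankrd44 (2.40) likewise rested on 1 of 4 probe sets, and their mean gave a bound of 0.52. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, was higher in both of its kept probe sets (2.35 and 1.71), and the mean of all its probe sets gave a bound of 1.27. Nexmif was higher in 4 of 4 (1.64 to 2.11). The endoderm transcription factor Sox17 was at least 5.10-fold higher; its second probe set did not reach the filter, and the mean of both gave a bound of 1.60. Srgn, which encodes the proteoglycan serglycin, had signals of 155 and 628 (4.36-fold higher). Zfp935 (2.18), Rhobtb1 (2.16) and Maff (2.11), a small MAF transcription factor, followed. Pgbd1, Gprc5c and Dock10 were at least 4.13-, 4.07- and 3.89-fold higher, and the mean of their probe sets gave bounds of 1.24 for Gprc5c and 0.88 for Dock10.

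The core pluripotency factors kept high and similar signals. Pou5f1 had signals of 8989 in shCtrl and 8619 in shSin3a-1, and its log2 difference was 0.05 after centring and -0.06 as deposited. Nanog (11657 and 11776, 0.12) and Sox2 (10033 and 10874, 0.22) differed by less than the spread between probe sets of 1 gene (SD 0.47 over 4410 genes). That SD pools bright and dim genes, and dim genes differed more often, so it is a wide yardstick for genes this bright. Of 26 pluripotency genes, 25 were within 2-fold in the brightest probe set. Gbx2, a homeobox gene downstream of LIF and STAT3, was the exception and was 3.08-fold higher, with signals of 1276 and 3647. Dimmer kept probe sets passed 2-fold, all higher, for Esrrb (1.18, against -0.15 in its brightest), Lin28a (1.09, against 0.14) and Fgf4 (1.00, against -0.06). The list's median was 0.10 (percentile 66.6) and -0.01 with the deposited scaling. Of 11 kept genes of formative and primed pluripotency, Otx2 (1459 and 443, -1.61) and Sall2 (-1.54) were lower and 8 were within 2-fold. Lef1 was 2.09-fold higher, but its difference was 0.95 as deposited and the mean of its probe sets gave -0.18 with 1 array at the floor. The median of this list was -0.24 (percentile 6.55), and it stood apart with the filter at the 75th percentile (-0.26, percentile 1.53) and against unmatched random lists (percentile 1.22).

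Both Lefty genes were lower, while 15 of 17 kept genes of the Nodal and Activin pathway were within 2-fold. Lefty1 had signals of 1552 and 511 (2.82-fold lower), and Lefty1 and Lefty2 were the only members past 2-fold in the brightest probe set. The 3 kept probe sets of Foxh1 disagreed, from -0.74 in the brightest to 1.61. The list's median of 0.05 (percentile 34.0) was -0.06 as deposited. Its mean of -0.21 had the opposite sign and lay at percentile 0.13, so that the list stood apart on the low side by its mean but not by its median. Among 8 kept BMP targets, Id1 (1.10) and Id2 (1.09), inhibitors of basic helix-loop-helix factors, were higher, and 7 of 8 members lay above 0. With the deposited scaling, Id1 (0.99) and Id2 (0.98) fell just short of 2-fold, and without probe sets of shared sequence Id2 was under the floor on both arrays. The BMP median was 0.38 (percentile 96.8), just inside the range of random lists. The list stood apart in 5 alternatives: with a looser filter (percentile 98.2), the mean of probe sets (99.1), unmatched random lists (97.7), the mean of the list (99.4) and random lists matched on gene span (98.4), the last added after the data were seen. Of 5 kept WNT targets Lef1 was at 2-fold, and the median of -0.07 (percentile 31.1) had the opposite sign to the mean of 0.17.

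Targets of LIF and STAT3 and of FGF and ERK were higher as lists. All 11 kept LIF-STAT3 targets lay above 0, with a median of 0.31 (percentile 98.4), although Gbx2 alone reached 2-fold; its percentile was 97.3 with a stricter filter on signal and 96.2 against unmatched random lists. With the deposited scaling Socs3, Pim1 and Tfcp2l1 turned below 0. Of 11 kept FGF-ERK targets 9 lay above 0 and the median was 0.39 (percentile 99.3), at 0.28 as deposited. Fos was 2.58-fold higher, Phlda1 2.02-fold and Dusp6, a phosphatase of ERK, 2.01-fold, with Dusp6 signals of 2290 and 4280. As deposited, Phlda1 (0.91) and Dusp6 (0.90) were under 2-fold. Etv5 (-0.19) and Ier3 (-0.33) were below 0.

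**Figure D2:**
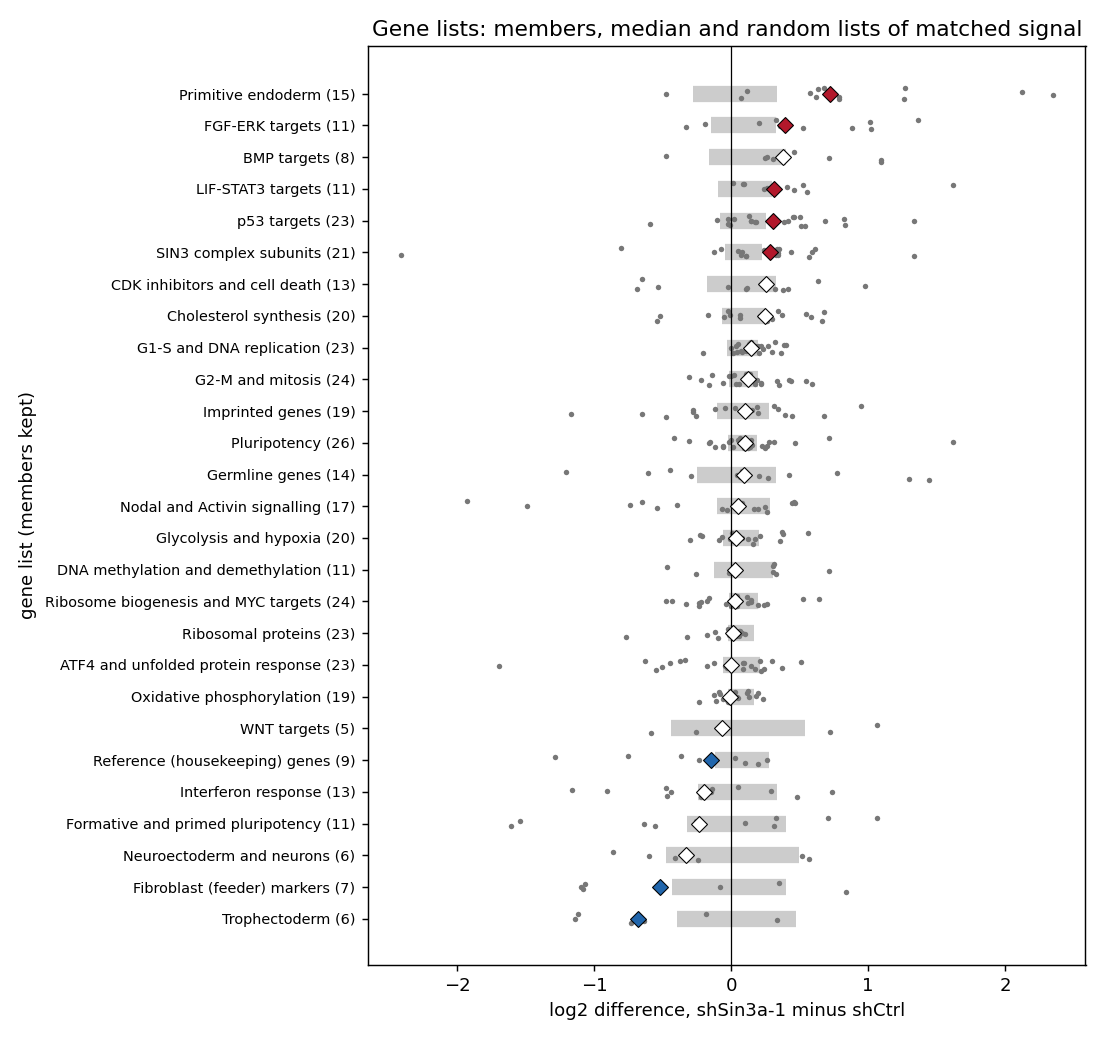
Rows are the 27 gene lists with at least 5 kept members (number in brackets), and the x axis gives the log2 difference, shSin3a-1 minus shCtrl after centring. Grey dots are genes, diamonds are list medians (red above the grey bar, blue below it, white otherwise), and grey bars span the central 95% of the medians of random lists matched on signal. Primitive endoderm (0.72) lies highest and trophectoderm (-0.68) lowest, and both keep these signs under every scaling, whereas the medians of pluripotency and ribosomal proteins change sign with the deposited scaling.

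Of the lineage lists, primitive endoderm stood furthest apart. Among its 15 kept members 14 lay above 0, and the median of 0.72 exceeded those of all 10000 random lists (percentile 100). Sox17, Srgn, Pdgfra (1.27), a receptor of platelet-derived growth factor, and Amn (1.26) passed 2-fold; Amn is outside the naming rule and was chosen after its value was seen. Gata6 (0.58), Lama1 (0.72), Lamb1 (0.79) and Col4a1 (0.62) were under 2-fold, and Hhex (-0.47) was below 0. Pdgfra was measured by a dim probe set, and the mean of its 3 probe sets was under the floor on both arrays. The median was 0.61 with the deposited scaling, under which Lamc1 also turned below 0. A further 8 members, among them Gata4, Foxa2 and Hnf4a, did not reach the filter.

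Of 22 trophectoderm genes on the array 6 were kept, and 2 of these passed 2-fold, both lower. Of the 6 kept members 5 lay below 0, with a median of -0.68 (percentile 0.05). Tfap2c, a transcription factor of trophoblast and germ cells, had signals of 1157 and 487 (-1.14), and Krt18, a simple epithelial keratin, had 541 and 231 (-1.12). Tfap2c was at -0.37 when probe sets of shared sequence were left out. The list no longer stood apart when dimmer genes were included (median -0.0027 at percentile 58.4 with the filter at the 50th percentile). The median of 6 neuroectoderm genes was -0.33 (percentile 8.57, or 1.49 against unmatched random lists), but it turned to 0.41 (percentile 96.6) with the filter at the 50th percentile and to 0.11 in the mean of probe sets, so the list has no stable direction. Sox1 (-0.86) differed most and was under the floor on both arrays in the mean of its probe sets. In the streak and mesoderm list, Bmp4 (0.71) alone was kept and 20 members were below the filter. Of 33 Hox genes on the array 1 was kept, Hoxa5 (-0.37).

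Of 7 kept fibroblast markers, Mmp2 (-1.10), Pdgfrb (-1.08) and Loxl1 (-1.07) were lower and the median was -0.52 (percentile 1.12), but Vim, an abundant intermediate filament gene, was at 0.83. The fibroblast list did not stand apart in the mean (-0.38, percentile 4.76) or without probe sets of shared sequence (-0.30, percentile 7.78), and its median was 0.38 over the few members left by the stricter filter. In the mean of its probe sets Mmp2 was at -0.92, Pdgfrb was at the floor on 1 array and Loxl1 on both.

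The remaining subunits of the SIN3 complex were on the whole slightly higher. Of 21 kept subunits 17 lay above 0, of which Rbbp4, Kdm5b and Sinhcaf turned below it as deposited. The median of 0.29 (percentile 99.7) included Sin3a and was 0.18 as deposited. Ing2, a subunit that binds methylated histone H3, was 2.52-fold higher, with signals of 1072 and 2509. The paralog Sin3b was at 0.34, Hdac2 at 0.24 and Hdac1 at -0.07. The list did not stand apart by its mean, which Sin3a lowers (0.13, percentile 70.6), or with the mean of probe sets (0.18, percentile 79.9). Among 11 genes of DNA methylation and demethylation none reached 2-fold in the brightest probe set. All 5 kept probe sets of Dnmt3a were lower, at -0.26 in the brightest and from -1.43 to -0.16 over all. Mbd2 was at 0.33 in its brightest probe set and at 1.19 in another. Tet1, a methylcytosine dioxygenase, had signals of 7241 and 8285 (0.30), and 4 of 4 probe sets were above 0. By brightest probe sets Dnmt3l differed most (0.71), and the list's median was 0.03 (percentile 29.5) and -0.08 as deposited.

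Germline genes differed in both directions. Dazl, an RNA-binding protein of germ cells, was 2.73-fold higher in its brightest probe set, with log2 differences of 1.45 and 1.40 in its kept probe sets, Slc25a31 was 2.46-fold higher and Mov10l1, a piRNA helicase, was 2.31-fold lower; Mov10l1 was under 2-fold with a higher floor (-0.88). The median of the 14 kept genes was 0.09 (percentile 63.2) and -0.02 as deposited. Of 19 kept imprinted genes, Phlda2 (-1.17) alone passed 2-fold in the brightest probe set, with a list median of 0.10 (percentile 58.5) and -0.01 as deposited. Peg3 was at 0.95 in its brightest probe set and reached 1.67 in another. Both kept two-cell-stage genes went opposite ways, Calcoco2 at -1.18 and Ddit4l at 0.65.

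Targets of p53 were higher as a list. Of 23 kept targets 18 lay above 0, with a median of 0.30 (percentile 99.2) and 0.19 as deposited. Aen turned below 0 with the deposited scaling. Pmaip1, which encodes the pro-apoptotic protein NOXA, was the single target past 2-fold by brightest probe sets (409 and 958, 1.34). Btg2 (0.82), Apaf1 (0.83) and Sesn1 (0.51) were under 2-fold by this measure. The classical targets Cdkn1a (-0.03) and Mdm2 (0.15) were near 0, Mdm2 with a sign that depended on the scaling. Other kept probe sets passed 2-fold, all higher, for Rrm2b (1.31), Apaf1 (1.08), Mdm2 (1.02) and Sesn1 (1.00). The list no longer stood apart when dimmer genes were included (0.24, percentile 96.5). None of 13 CDK inhibitors and cell death genes passed 2-fold in the brightest probe set (median 0.25, percentile 92.7). Bcl2l11, which encodes BIM, came closest (0.98), and its 3 kept probe sets were all higher, up to 1.11. Cdkn1b was at 0.11 in its brightest probe set and at 1.40 in another.

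Proliferation genes were similar on both arrays. None of 23 genes of the G1-S transition and DNA replication (median 0.15, percentile 89.6, Slbp at 0.40) and none of 24 genes of G2-M and mitosis (median 0.12, percentile 77.1, Kif23 at 0.59) reached 2-fold. Slbp turned to -0.20 in the mean of its probe sets. These counts refer to brightest probe sets, and other kept probe sets of Cenpf (1.38) and Kif23 (1.06) passed 2-fold. Ribosome biogenesis and MYC targets had a median of 0.02 (percentile 12.4, Nop16 at 0.64) and -0.08 as deposited, with none of 24 at 2-fold.

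Among metabolic and stress lists, none of 20 cholesterol synthesis genes reached 2-fold (median 0.24, percentile 96.6); the list stood apart with the filter at the 75th percentile (0.27, percentile 97.9) and among random lists matched on gene span, added after the data were seen (percentile 98.4). Msmo1 (0.68) differed most there and was at -0.25 without probe sets of shared sequence. Glycolysis and hypoxia genes (20 kept, median 0.04, percentile 28.8) had a median of -0.07 as deposited, and Pdk1 was at 0.56 and at 1.41 in the mean of its probe sets. Oxidative phosphorylation genes (19 kept) had a median of -0.01 at percentile 5.26 and a mean of 0.02. Nupr1, a stress-induced chromatin protein, was 3.24-fold lower in the ATF4 and unfolded protein response list, with both probe sets lower. The other 22 members were within 2-fold in the brightest probe set, though Trib3 reached -1.09 in another. The median of this list was at percentile 13.5 and its mean (-0.11) at percentile 1.32. Of 13 interferon response genes, Psmb9 (-1.16) was lower, and it was under 2-fold with an offset before log2 (-0.98). Ifitm3 (-0.91) was within 2-fold after centring but passed it, also lower, under every other scaling (-1.03 to -1.01). The median of the interferon genes was -0.20 (percentile 4.56). The interferon list stood apart with the filter at the 75th percentile (-0.44, percentile 0.03) and against unmatched random lists (percentile 1.53).

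The lists meant as references were close to 0 with exceptions. Of 23 kept ribosomal protein genes none passed 2-fold, with a median of 0.01 (percentile 10.8) that was -0.09 as deposited, and a mean of -0.04 that stood apart (percentile 0.74); Rpl14 differed most (-0.77). Of 9 kept reference genes, Gusb was 2.44-fold lower, with signals of 795 and 302, and its second probe set was at -0.38. Actb was at 0.10 and at -0.01 as deposited. The reference list stood apart on the low side (median -0.15, percentile 1.29), but not against unmatched random lists (percentile 6.29) or with the stricter filter (-0.06, percentile 6.13). In all, 8 of 27 lists stood apart, where about 1.35 would be expected of randomly drawn genes. Members of a list can vary together between any 2 cultures, which random lists do not reflect. With 1 array per group the count is therefore not an excess over ordinary differences between cultures, and several lists share genes.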

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

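The tests on the 18S control probe sets below were chosen after the result was seen. Control probe sets for 18S ribosomal RNA, which enter no comparison, were higher on the shSin3a-1 array than on the control array. Their median log2 difference was 1.69 (3.24-fold), and 3 of 3 were higher, from 1.12 to 1.92, with signals of 2488 and 8737, 4987 and 14963, and 8695 and 17515. A scaling or labelling difference between the whole arrays is argued against by the spike-in controls, whose median difference over 42 probe sets was 0.11 after centring, or 6.25% of that of 18S, and -0.0028 as deposited, where 18S was at 1.59. Of the 42, the 18 hybridisation spike-ins bear on scaling only, and the 24 poly-A spike-ins bear on labelling too. The poly-A spike-ins had a median of 0.12 after centring and 0.0158 as deposited. They ran from -0.08 to 0.64 after centring, under the lowest 18S value. The centred value of the 42 spike-ins is about the centring shift itself, so they lie closer to the deposited scaling. More ribosomal RNA carried into the labelling of 1 sample remains open, because 3 of 3 probe sets differ together and no other value on the arrays measures ribosomal RNA; with 1 array each it cannot be told apart from a difference that comes with the shRNA, which was not tested.

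The control probe sets for the transferrin receptor, also outside every comparison, were higher on the shSin3a-1 array than on the control array, with a median log2 difference of 1.38 over 3 probe sets (1.02 to 1.49). The named probe sets of the same gene, Tfrc, were at -0.15 for the brightest (signals 8096 and 6773), 0.91 and 2.16.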

How the results depend on the processing

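Random lists matched on gene span and the filter at the 90th percentile were chosen after seeing the data; all other alternatives were fixed beforehand. With 1 array per group no paired analysis or omission of a replicate was possible. Sin3a stayed lower in all 13 alternatives (-2.55 to -2.11). Primitive endoderm (percentile 99.85 to 100) and FGF-ERK targets (98.45 to 99.97) stood apart in every alternative run. The number of higher genes was 156 with scaling on the 75th percentile, 99 and 19 with filters at the 75th and 90th percentile, 997 at 1.5-fold, 49 at 3-fold and 551 when all kept probe sets had to share a direction, where by construction any of them may pass. The number of lower genes was 312 with the filter at the 50th percentile or none, 59 and 10 with filters at the 75th and 90th, 122 with an offset, 661 at 1.5-fold and 29 at 3-fold. Filters and thresholds change counts by construction. So do scaling on the 75th percentile, which shifts every difference alike, and an offset, which shrinks log2 differences, most for dim genes. For the other changes given here the cause was not tested. With the filter at the 50th percentile the medians were -0.0027 for trophectoderm (percentile 58.4) and 0.24 for p53 targets (96.5), and with no filter -0.0604 (47.6) and 0.18 (89.1), where -0.0604 is the difference of the floors, so the middle gene was not measured; the fibroblast list without filter was also at -0.0604 (49.6). With the filter at the 75th percentile the fibroblast median turned to 0.38 over too few genes for a percentile, reference genes were at -0.0605 (6.13) and LIF-STAT3 targets at 0.29 (97.3). Without probe sets of shared sequence LIF-STAT3 was at 0.32 (97.3) and fibroblast at -0.30 (7.78). Unmatched random lists gave percentiles of 96.2 for LIF-STAT3 (0.31) and 6.29 for reference genes (-0.15), and loess put reference genes at -0.23 (2.52). The mean of a list gave 0.13 for SIN3 subunits (70.6), -0.38 for fibroblast (4.76) and -0.21 for Nodal and Activin genes, which then stood apart (0.13). The mean of probe sets gave 0.18 for SIN3 subunits (79.9) and -0.18 for Lef1, with 1 array at the floor. Pdgfra in the mean of probe sets and Id2 without shared-sequence probe sets were under both floors (-0.0604) and showed no direction. Of 845 alternative values of the other named genes 800 moved by less than the SD between probe sets and 42 by more. Another 3, of genes at 2-fold, changed sign. Of these 2, and of the 42 another 5, had both arrays under the floor and measured nothing. Filters cannot change a gene's value and scalings shift it little, so many of the 800 could hardly move. Among the 800 and 42 another 7 values, of genes under 2-fold (Pou5f1 in 4 scalings, Slbp, Sdha and Msmo1), also changed sign. In all, 31 of 50 named genes at 2-fold kept a value of 2-fold or more in every alternative. This count ignores stricter filters: Sox17 counts although its brighter signal of 221 lies under the 75th percentile of the shSin3a-1 array (415). Of 317 values of the other lists 300 stayed on the same side of the percentile limits or, without a percentile, moved by less than that SD, 14 newly stood apart and 3 moved. The sign changed in 37 of the 317, in 12 lists; in 33 of the 37 the main median was within 0.1 of 0, and the others were neuroectoderm (0.41 at percentile 96.6 with the filter at the 50th percentile, 0.11 in the mean of probe sets), the two-cell-stage list and, without filter, the streak list at the difference of the floors. Signal over background limits the dim genes.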

Other observations

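The tests on primitive endoderm and on RNA degradation below were chosen after the result was seen, and the genes in the next paragraph were chosen after their values were seen. The test of signal dependence was written beforehand.

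The low level of Ccnd2 did not extend to the other D-type cyclins: Ccnd1 was at -0.26 (signals 4455 and 3455) and Ccnd3 at 0.47 (4954 and 6342), with signs kept under every scaling. Gli1 (403 and 119, -1.65) and Ptch1 (2213 and 908, -1.18), which Hedgehog signalling induces, were lower, while Gli2 was at -0.08. Ifitm1, an interferon-induced membrane protein, was 3.32-fold lower (6385 and 1784, -1.73), while Ifitm2 (-0.29) was within 2-fold. Ifitm3 (5351 and 2644, -0.91) was within 2-fold after centring only, and passed it under the 4 other scalings (-1.03 to -1.01). Trh, the precursor of thyrotropin-releasing hormone, was 3.39-fold lower with signals of 2517 and 688, and Fgf17 (-1.06) and Fgf15 (-1.18) were lower while Fgf4 was at -0.06. The metallothionein Mt1 was 2.11-fold lower (5931 and 2601, -1.08), and Mt2 (11418 and 5948, -0.83) was within 2-fold. Sox11, a transcription factor of neural progenitors, was 3.81-fold higher with signals of 282 and 998, Tcl1b3 was 3.32-fold higher while Tcl1 was at -0.06, and the heat shock gene Hspa4l was 3.26-fold higher.

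The primitive endoderm genes were higher together (median 0.72). A trend of the difference with gene span is argued against as the whole cause, since the list lay at percentile 99.99 among random lists matched on signal and span. RNA from feeder fibroblasts is argued against by the fibroblast collagens Col1a1, Col1a2 and Col3a1, whose highest signal in shSin3a-1 was 49.6 where a kept gene needed 126, and the labels describe gelatin-coated plates. A larger share of primitive-endoderm-like cells may account for it. Without the members past 2-fold the other 11 had a median of 0.63 (percentile 99.93). Not all of them rose, though: Hhex was at -0.47, and the secreted proteins Lamc1 (0.07) and Sparc (0.12) were near 0. Bulk arrays of 1 culture each cannot tell such cells apart from a higher level in every cell, and an effect of the knockdown stays open and untested.

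Longer genes tended to be higher. Across 9769 kept genes the log2 difference correlated with annotated gene span (Spearman's rho 0.14 across genes, which are not independent replicates). In the longest span quintile, of median 108 kb, 87 genes were at least 2-fold higher and 25 lower; in the shortest, of median 4.59 kb, 40 were higher and 59 lower, counts that move with the scaling. A signal-dependent difference between the arrays is argued against by a rho of 0.13 (median) within deciles of signal. More degraded RNA on the control array could contribute and cannot be told apart from an effect of the knockdown. The 3' to 5' ratios of GAPDH and beta-actin were lower on the shSin3a-1 array by log2 differences of -0.03 and -0.14. This is the direction degradation needs, but both fell far short of the size set for it, and they rest on 2 transcripts. The transferrin receptor control, with 3' and 5' signals of 277 and 60.4 in shCtrl and 522 and 146 in shSin3a-1, did not enter the test. Its ratio was also lower on the shSin3a-1 array, by more than those of GAPDH and beta-actin, though its 5' signal in shCtrl was dim.

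Of 2059 kept probe sets without a single gene symbol, 70 were at least 2-fold higher and 108 lower. Kept probe sets of 7 genes (Atg4a, Crat, Lims1, Map2k5, Msi2, Sipa1l1 and Slc38a10) differed by 2-fold in opposite directions within the gene.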
